A study of Mus musculus with 6 samples.

How the data were processed

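RNA from 3 wild-type and 3 Thbs1 knockout samples of diaphragm from mice on a high-fat diet was made into single-end 3' mRNA libraries, per the labels' protocols. The submitters' processing notes list cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3, and the genome build GRCm38. The gene annotation is not given in the sources used here. The table deposited by the authors is named as one of expected counts per gene.

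Samples were assigned to genotypes by their titles. The names of the table's value columns were then compared with every text of the labels, ignoring case and punctuation. 0 columns matched a sample and 6 did not, and these 6 columns were not used. The differential expression test, the gene list tests and the tests of calls near Thbs1 that were fixed before the data were examined all need the genotype of each column, so none was run. The rule for named genes, which ranked genes by that test, consequently named Thbs1 alone. The plan also held principal components of the libraries, correlations between libraries, and counts of calls for other splits of the libraries. These can be computed without a genotype. They were not run either, because no column could be tied by its name to a sample.

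The value columns were inspected when the format and unit of the table were examined, the row of Thbs1 included, and no value from them enters a result. Of the table's contents, the results use only the identifier columns and the names of the value columns. The position and structure of Thbs1 came from the GENCODE M21 annotation alone. Gene identifiers were joined without their version suffix to the GENCODE M21 annotation of GRCm38, the build in the submitters' processing notes. Positions are counted as in a genome browser. Genes near Thbs1 were those of the table that overlap a window extending 10 Mb from either end of Thbs1, with windows of 5 Mb and 20 Mb as alternatives. Gene list members were matched by symbol, with older symbols accepted. Python 3.11.15 and pandas 2.3.3 were used.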

Results

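The series holds 6 samples of diaphragm muscle from mice fed a high-fat diet for 6 months, with 45% of dietary energy from lipid. The diaphragm is the main muscle of inspiration. 3 libraries came from wild-type C57BL/6J mice and 3 from mice labelled as knockouts of Thbs1, which encodes the secreted matricellular glycoprotein thrombospondin-1. The knockout mice were of the strain B6.129S2-Thbs1tm1Hyn/J. Polyadenylated RNA was profiled with a kit that primes at the poly(A) tail and reads the 3' ends of transcripts. The title of the series names stromal expansion and contractile function of the obese diaphragm as its subject, and the design implies a single comparison, knockout against wild type on the same diet.

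That comparison was not made here. The deposited table holds 6 columns of per-library values under library codes. None of these codes occurs in the labels of the 6 samples, and the titles restart their replicate numbers within each genotype, so a code matched neither a single sample nor a genotype. The order of the columns was not taken as a substitute for a label, and the values were not used to infer a genotype. No fold change or test between genotypes could therefore be given. Expression levels and sequencing depths do not need a genotype, but they were not analysed here either, because no column could be tied by its name to a sample of the series.

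The targeted gene, Thbs1, lies on the forward strand of chromosome 2 at positions 118111876 to 118127133 of GRCm38. The GENCODE M21 annotation gives it 2 transcripts. The transcript with the longest coding sequence has 22 exons. Its last exon spans positions 118125022 to 118127133 and is 2112 bases long. The annotated 3' untranslated interval begins at position 118125027, includes the stop codon and is 2107 bases long, so nearly the whole last exon is untranslated.

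The table lists 55491 genes by Ensembl identifier, with 0 duplicated identifiers. 55141 of them, 99.4%, have a position in GENCODE M21, and 350 do not. The table includes all 619 distinct genes of the 39 gene lists drawn up for the planned analysis. Some of these lists hold markers of other tissues, such as liver and heart. Among the lists are 14 collagens, mostly fibrillar or fibril-associated, 23 markers of fibro-adipogenic progenitors and fibroblasts, and 22 white adipocyte markers. Others hold 15 fast-fibre contractile genes, 14 slow-fibre contractile genes, and 21 genes of TGF-beta signalling, among them ligands, receptors and response genes. Presence in the table says only that a gene was annotated, not that it was expressed.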

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

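Calls near Thbs1 were to be tested because DNA next to the knockout allele may still derive from the strain of the embryonic stem cells. No such test was run, and the counts below are of annotated genes only. The window of 10 Mb on either side of Thbs1 held 407 other genes of the table, 241 of them protein-coding. A window of 5 Mb held 226 genes and a window of 20 Mb held 739, as a longer window takes in more genes. The other settings chosen before the data were examined, on normalization, filters, the choice of test and libraries left out in turn, were not run because they need the genotype of each column. No paired analysis was possible because the columns carry neither a genotype nor a replicate number from the titles. The titles also do not say that equal replicate numbers mark paired mice, so labelled columns alone would not have defined pairs.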
